A study of Mus musculus with 8 samples.

How the data were processed

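RNA from fresh-frozen livers of 8 female B6C3F1 mice, 4 given corn oil and 4 given furan at 8 mg per kg body weight by gavage on 21 days, was measured on the 8 arrays of 1 slide, Agilent array design 028005. The label text mentions other doses in the wider experiment, and these are not analysed here. The scanner files hold, per the file headers, the fluorescence intensity of each spot from 1 scan of 1 colour by Agilent Feature Extraction 11.0.1.1, with a processed intensity after background subtraction and detrending, and median intensities of each spot and its local background without them. The deposited value table of the authors is in log2 units. Its method is not given in the sources used here. Its columns follow the log2 median spot intensity of the same array, after a smooth shift that depends on the array and the intensity, with a correlation across probes of 0.998 for vehicle replicate 2 and of 1.00 for the other 7 arrays. Probes are not independent replicates.

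Each array held 62976 spots, of which 3671 were controls and were left out. Spots that the scanner software marked as outliers, 128 to 315 on each array, were left out, and 0 spots were saturated. The log2 processed intensity was shifted to the 75th percentile of its array, and spots of 1 probe were averaged. A probe was kept if it was well above background on at least 4 of the 8 arrays whatever the group, which left 33848 of 55681 probes. Each gene was represented by its kept probe with the highest mean over all 8 arrays, giving 24921 genes or transcripts. The scanner files carry no gene names. Symbols were taken from the RefSeq accession of each probe through a table for assembly GRCm38.p6, which gave one to 27235 of the 28685 probes with such an accession. The probe annotation of the array is against another build, so no positions are given. Of the tested features, 15070 had a symbol and 9851 did not, and 3770 of those with a symbol had several kept probes.

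The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all 24921, and a gene passed at an adjusted p under 0.05. Fold thresholds were 1.5 and 2. The label text names a randomized block design without saying which animals share a block, so the fit had 1 group term. The 41 gene lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 41 lists, with an estimated correlation and with fry as alternatives. The 111 features with a missing value were left out of the list tests. Ahsp of the erythroid list was not used here. An "at least N-fold" change was computed for genes that were well above background on no array of 1 group, against the lowest signal well above background on each array of that group.

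The lists, the tests, the rule for named genes and all alternatives except 2 were chosen before the data were examined. Named genes were the 10 largest increases and 10 largest decreases past the threshold with an ordinary symbol and no overlap between groups, up to 4 members with the smallest adjusted p from each list past the camera threshold, up to 2 from each other list, and 14 genes fixed in advance. Some genes that this rule names are not reported here. The alternatives were quantile normalization, a median shift, no shift, normexp with an offset of 50 followed by quantile normalization, the authors' value table, no filter, a filter on all 8 arrays, outlier-marked spots kept, each probe on its own, the mean of the probes of a gene, eBayes with trend and robust, array weights, the slide row or column as a block, each array left out, an adjusted p under 0.01, treat against 1.5-fold, and 2-fold. The files hold no mean spot intensity, so normexp was run on the median spot intensity. A shift by the brightest 25% of genes and a fit of the brighter 50% of genes were added after the data were seen. Counts were also compared over the 35 splits of the 8 arrays into groups of 4.

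The limma fit was tested on simulated values, with 200 changed genes among 24921. It recovered 14 of 67 genes changed 1.5-fold, 31 of 67 changed 2-fold and 52 of 66 changed 4-fold, with 4 false calls. The scaling, the filter and the choice of probes were not part of this test. The simulated noise was normal and independent between genes and arrays, without a shift of any array. The false calls in the real data may therefore differ. The number of arrays limits the precision of each value. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.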

Results

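Liver RNA of 8 female B6C3F1 mice was measured on 8 one-colour Agilent arrays. The vehicle group, 4 animals with replicates 2, 3, 4 and 6, received corn oil by gavage, and the furan group, 4 animals with replicates 41, 42, 43 and 44, received furan at 8 mg per kg body weight. Furan is a small volatile compound formed when food is heated, and it is toxic and carcinogenic in rodent liver. Dosing ran for 21 days, and the livers were taken 4 hours after the last dose and frozen fresh. Between 55.1% and 86.2% of the 59305 probe spots on an array were well above background, the highest share being on the array of vehicle replicate 2. After filtering, 24921 genes or transcripts were tested, of which 15070 had a current gene symbol. The number of arrays, 4 in each group, limits the precision of each value. Levels are log2 signals relative to the 75th percentile of their array, and each change is furan minus vehicle.

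The comparison of furan with vehicle asked which liver genes differed after 3 weeks of exposure. Of 30 measured targets of the tumour suppressor p53, 15 rose and 1 fell, led by the cell cycle inhibitor gene Cdkn1a at 25.2-fold and the growth-restraint gene Phlda3 at 12.3-fold (adjusted p = 0.0626 for the list with an estimated correlation). Of 34 genes driven by the oxidative stress regulator NRF2, 13 rose and 0 fell, among them Nqo1 at 2.55-fold (adjusted p = 0.173 with an estimated correlation). Of 32 genes of G2/M and mitosis 12 rose (adjusted p = 0.409 with an estimated correlation). Of 21 heat shock genes 7 rose, of 24 immediate early genes 5, and of 23 fetal or tumour-associated liver genes, such as Afp, 5 (adjusted p = 0.0626 for each with an estimated correlation).

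In limma with Benjamini-Hochberg adjustment, 1041 genes or transcripts passed an adjusted p of 0.05, 714 of them higher and 327 lower. With the slide column as a block, each column holding 1 vehicle and 1 furan array, limma called 0, and 4723 had an unadjusted p under 0.05. Of the 1041, 786 had a symbol, and 631 changed at least 1.5-fold, 405 upward and 226 downward. The largest named decrease was that of the fatty acid elongase gene Elovl3, at 5.09-fold (adjusted p = 0.0359). It was 2.30-fold lower with normexp (0.0431) and 2.46-fold lower in the authors' value table (0.0322), and did not pass with a median shift (0.0670), without a shift (0.0720), without the filter on dim probes (0.0958) or with the slide row as a block (0.0557). The Elovl3 call held only without vehicle replicate 6 among the 8 fits that left out 1 array. Its adjusted p was 0.0531, 0.0759 and 0.0755 without vehicle replicates 2, 3 and 4, and 0.101, 0.0950, 0.0767 and 0.0919 without furan replicates 41, 42, 43 and 44.

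**Figure D1:**
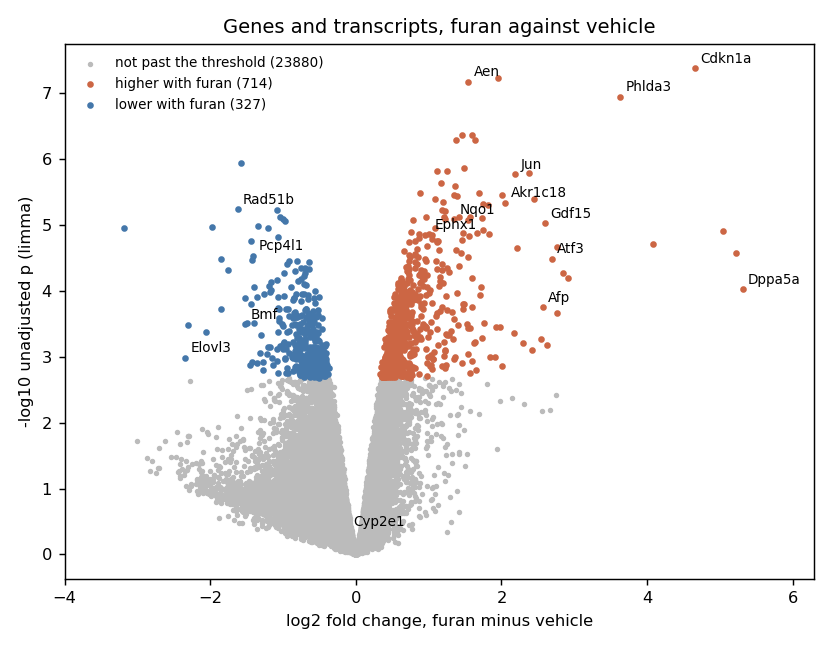
Each point is 1 of the 24921 genes or transcripts tested, with the log2 fold change of furan minus vehicle on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis, 4 arrays a group. The 714 higher and 327 lower genes are coloured, and Cdkn1a at a log2 fold change of 4.66 stands at the top right.

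Among the 41 gene lists fixed before the data were examined were p53 targets. Of the 30 measured p53 targets, 15 rose and 1 fell (16 and 1 adjusted over the list alone), and the median log2 fold change was 0.95 (adjusted p = 0.0626 with an estimated correlation). Cdkn1a, which blocks cyclin-dependent kinases, went from -2.27 ± 0.45 (SD, n = 4) on the vehicle arrays to 2.39 ± 0.20 on the furan arrays, a change of 4.66 ± 0.23 (SE, limma adjusted p = 0.000559). Phlda3, a repressor of the survival kinase Akt, rose by 3.63 ± 0.20 (adjusted p = 0.000712). Aen, an apoptosis-enhancing nuclease, rose by 1.55 ± 0.08 and Zmat3, a p53-induced zinc finger gene, by 1.64 ± 0.11. The p53-degrading ubiquitin ligase gene Mdm2 was 2.18-fold higher and the cyclin gene Ccng1 2.55-fold higher. Gdf15, a secreted stress cytokine, and Tnfrsf10b, a death receptor, rose by 2.60 ± 0.26 and 2.45 ± 0.22. The 1 member that fell was Ddb2, a DNA damage recognition gene, by 0.47 ± 0.10, named after its value was seen. Each of the named members except Ddb2 stayed past the threshold without any 1 array. A second Cdkn1a probe that passed the filter went the other way, with a log2 fold change of -0.59, and the mean of both probes gave 2.03 (adjusted p = 0.0562). With normexp the log2 fold changes of Cdkn1a and Tnfrsf10b were 3.92 and 1.73, and in the authors' value table that of Cdkn1a was 3.92.

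Of 34 measured NRF2 target genes, 13 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.57 (adjusted p = 0.173 with an estimated correlation). Nqo1, a quinone reductase gene, rose by 1.35 ± 0.13 (adjusted p = 0.00501). Ephx1, the microsomal epoxide hydrolase gene, went from 7.74 ± 0.15 to 8.74 ± 0.10, and the carbonyl reductase gene Cbr1 rose by 0.81 ± 0.09. The glucuronosyltransferase gene Ugt2b35 was 2.16-fold higher, and the genes of this family are close paralogues. These 4 calls held without any 1 array. Gclc, which encodes the catalytic part of the enzyme that starts glutathione synthesis, was 1.71-fold higher (adjusted p = 0.0224), a call that ended in 6 of the 8 fits that left out 1 array, at adjusted p of up to 0.0734 without furan replicate 43. Hmox1, the heme oxygenase gene, had a log2 fold change of 1.41 ± 0.39 and did not pass the threshold (adjusted p = 0.0849), except with trend and robust (0.0357).

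**Figure D2:**
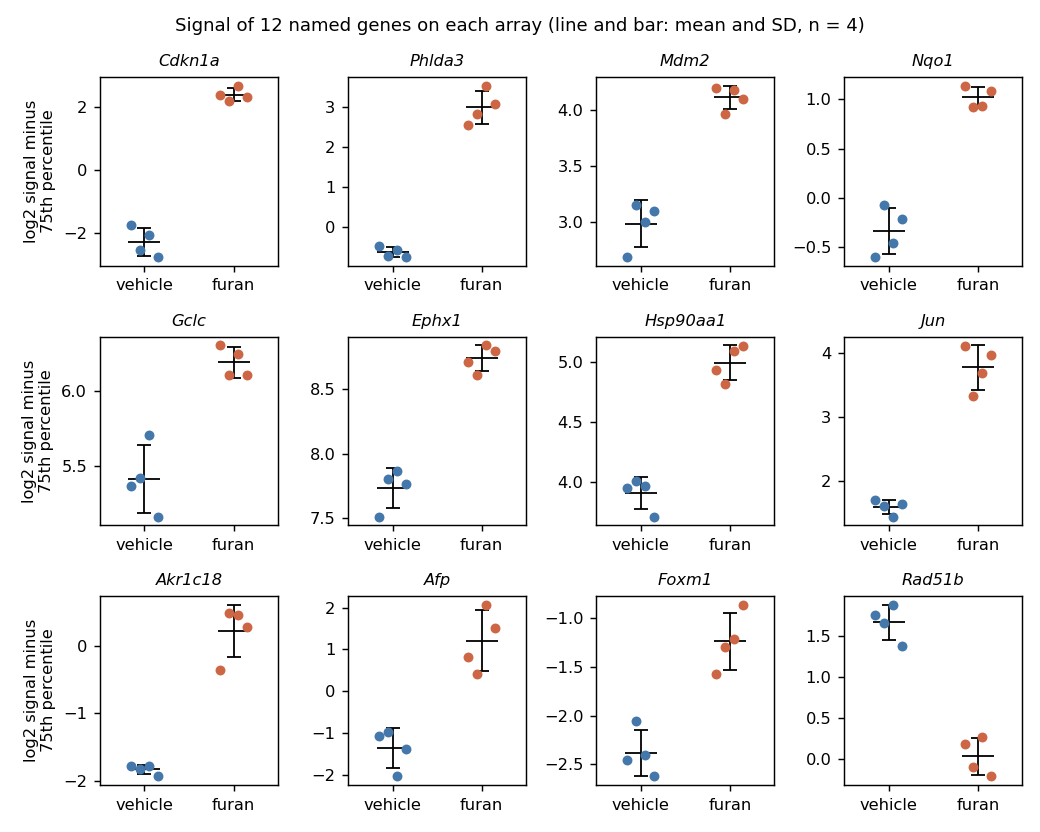
Each dot is 1 array, with the log2 signal minus the 75th percentile of its array on the vertical axis, and the line and bar are the mean and SD of 4 arrays. Cdkn1a lies at a mean of -2.27 on the vehicle arrays and 2.39 on the furan arrays, and Rad51b runs the other way, from 1.66 to 0.04.

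Of 32 measured genes of G2/M and mitosis, 12 rose and 0 fell (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.92 (adjusted p = 0.409 with an estimated correlation). Mad2l1, a spindle checkpoint gene, rose by 0.97 ± 0.09, the cytokinesis gene Ect2 by 1.24 ± 0.18, the mitotic transcription factor gene Foxm1 by 1.15 ± 0.18 and the kinesin gene Kif22 by 1.31 ± 0.22. Of these, only Mad2l1 passed in each fit without 1 array, and its other 2 probes gave -0.23 and 0.43. Of 33 measured genes of G1/S and DNA replication, 1 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of 0.33 (adjusted p = 0.634 with an estimated correlation). Without vehicle replicate 4 that median was 0.16. The replicative helicase gene Mcm6 was 2.08-fold higher (adjusted p = 0.0371). Mcm6 did not pass in any fit without 1 array, at adjusted p of 0.0508 without furan replicate 42 to 0.0943 without furan replicate 44. The proliferation marker gene Mki67 had a log2 fold change of 0.96 ± 0.27 (adjusted p = 0.0857) and the cyclin D1 gene Ccnd1 one of 0.46 ± 0.20 (adjusted p = 0.215), neither past the threshold. Mki67 did pass in the authors' value table and with trend and robust (limma adjusted p = 0.0438 and 0.0400).

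Stress response genes formed 3 further lists, which share members with each other and with other lists. Atf3 is in both the immediate early and the unfolded protein and integrated stress lists. Of the latter list, Sesn2 is also a p53 target and Fgf21 also a fatty acid oxidation gene. Ephx1 is in both the p53 and the NRF2 lists. Of 21 measured heat shock genes, 7 rose and 0 fell (13 and 0 adjusted over the list alone), with a median log2 fold change of 0.38 (adjusted p = 0.0626 with an estimated correlation). The inducible chaperone gene Hsp90aa1 rose by 1.08 ± 0.11 and the chaperone gene Hspa4l by 0.95 ± 0.10. The co-chaperone genes Hsph1 and Chordc1 were 1.80-fold and 1.70-fold higher. Of 24 immediate early genes, 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.66 (adjusted p = 0.0626 with an estimated correlation). Jun, a subunit of the AP-1 transcription factor, rose by 2.19 ± 0.17 (adjusted p = 0.00306), the stress-induced factor gene Atf3 by 2.69 ± 0.32, and the MAP kinase phosphatase gene Dusp6 by 1.70 ± 0.24. Fosl2 rose by 1.18 ± 0.14 with the probe tested, but its other probe went to -1.21. The growth regulator gene Myc had a log2 fold change of 1.42 ± 0.33 and did not pass (adjusted p = 0.0550). Nor did it pass in any fit without 1 array (lowest adjusted p 0.0561). It did pass with array weights (0.0338), trend and robust (0.0190), normexp (0.0458), the filter on all 8 arrays (0.0308) and in the authors' value table (0.0318). Of 31 genes of the unfolded protein and integrated stress responses, 5 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.27 (adjusted p = 0.511 with an estimated correlation). The rising members included Atf4, a master regulator of the integrated stress response, at 1.55-fold and Sesn2, an inhibitor of mTORC1 signalling, at 1.96-fold. Chac1, a glutathione-degrading enzyme gene, fell by 1.32 ± 0.25 on the log2 scale. The Chac1 call held only without vehicle replicate 2, with adjusted p of 0.0763, 0.0855 and 0.0875 without vehicle replicates 3, 4 and 6 and 0.0991, 0.0662, 0.0643 and 0.0580 without furan replicates 41, 42, 43 and 44. The Atf4 call was lost without vehicle replicates 3 and 6 (0.0526 and 0.0582) and without furan replicates 41, 42 and 43 (0.0656, 0.0616 and 0.0644).

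Of 23 measured fetal and tumour-associated liver genes, 5 rose and 0 fell (10 and 0 adjusted over the list alone), with a median log2 fold change of 0.54 (adjusted p = 0.0626 with an estimated correlation). Akr1c18, a progesterone-metabolising reductase gene, rose by 2.05 ± 0.19, the tetraspanin gene Cd63 by 1.66 ± 0.17 and the Golgi protein gene Golm1 by 1.16 ± 0.15. Afp, which encodes the fetal serum protein alpha-fetoprotein, went from -1.36 ± 0.48 to 1.21 ± 0.73 (adjusted p = 0.0177). The Afp call ended without vehicle replicate 6 and without furan replicates 41 and 44, at adjusted p of 0.0536, 0.0503 and 0.0559, with log2 fold changes of 2.56, 2.69 and 2.46.

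These lists were called by camera with a preset correlation of 0.01, which put 18 of the 41 past an adjusted p of 0.05. The adjusted p was 4.09e-14 for p53 targets, 2.72e-14 for NRF2 targets, 2.56e-14 for G2/M, 3.00e-11 for heat shock, 2.10e-06 for immediate early, 2.77e-05 for unfolded protein and integrated stress, 0.000164 for G1/S and 9.19e-07 for fetal and tumour-associated genes. With an estimated correlation 0 of the 18 calls held in camera. Regrouping the 8 arrays at random gave 18 or more called lists in 16 of 35 splits, the real one included, so the number of called lists alone does not separate the groups. The fry test, which asks whether the genes of a list move one way on balance, put the first 6 of these lists and the fetal list past the threshold, 7 in all.

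**Figure D3:**
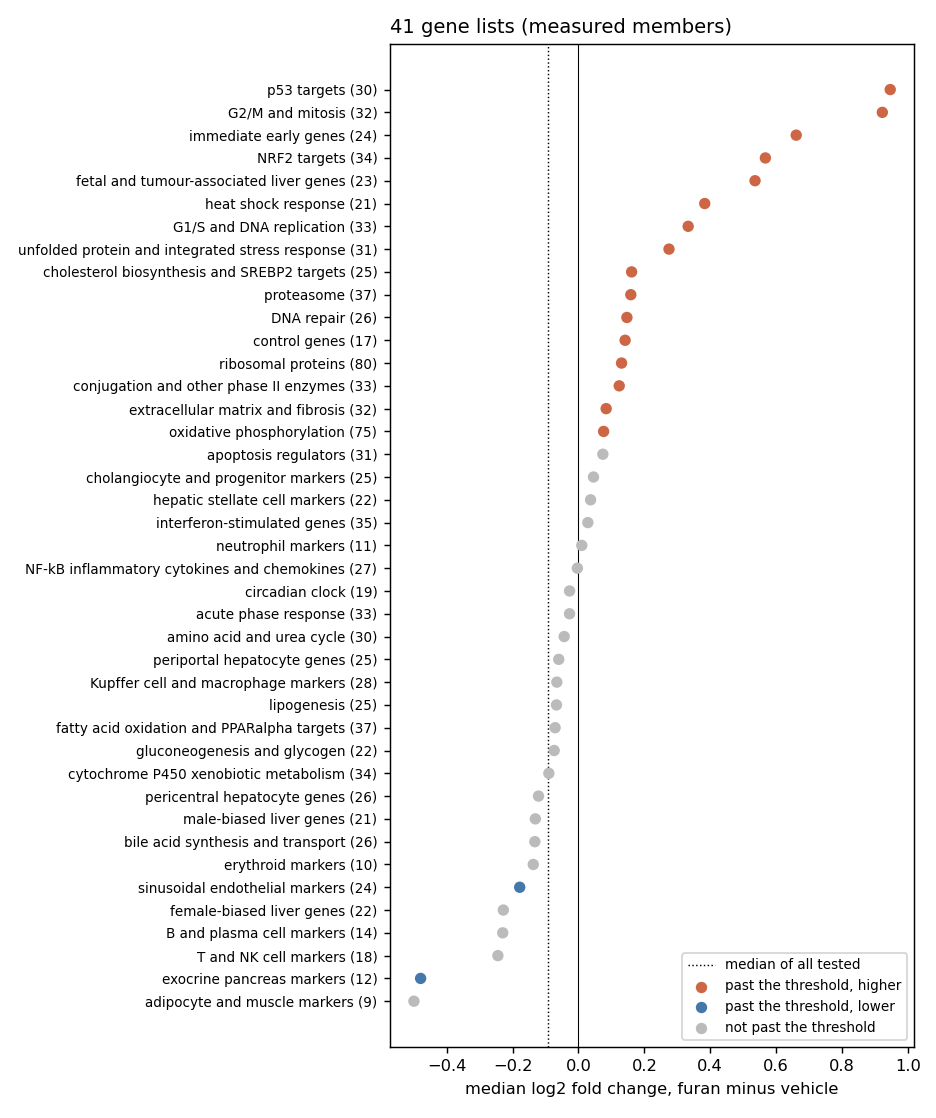
Each dot is the median log2 fold change of furan minus vehicle over the measured members of 1 of the 41 gene lists, with the number measured in brackets and colour showing the camera call at the preset correlation. The p53 targets lie highest at 0.95, and the dotted line marks the median of all tested genes at -0.09.

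The other 10 lists that passed camera had between 0 and 8 members past the threshold. Ribosomal protein genes, taken by a pattern on gene names, had a median log2 fold change of 0.13 with 2 of 80 higher (1 adjusted over the list alone), namely Rps27l and Rpl7l1 (adjusted p = 0.680 with an estimated correlation). The Rps27l call held in 0 of the 8 fits that left out 1 array, and the Rpl7l1 call in 2. In the authors' value table Rps27l did not pass (limma adjusted p = 0.0998). Proteasome genes had a median of 0.16 with 2 of 37 higher (2 adjusted over the list alone), Psmd14 and Psmd5 (0.680 as the adjusted p with an estimated correlation). Oxidative phosphorylation genes had a median of 0.08 with 0 of 75 past the threshold (0 adjusted over the list alone), and adjusted p = 0.913 with an estimated correlation. Control genes, chosen as commonly used references, had a median of 0.14 with 2 of 17 higher (2 adjusted over the list alone), the transferrin receptor gene Tfrc at 2.54-fold and the glucuronidase gene Gusb at 1.42-fold (adjusted p = 0.623 with an estimated correlation). These 4 lists were not past the threshold in the authors' value table, where the ribosomal, proteasome and oxidative phosphorylation medians were 0.01, 0.05 and -0.04. With a shift on the brightest 25% of genes the oxidative phosphorylation median was -0.03. Of DNA repair genes, 2 of 26 were higher (2 adjusted over the list alone), among them the flap endonuclease gene Fen1 at 1.37-fold (adjusted p = 0.634 with an estimated correlation). The Fen1 call held in 1 of the 8 fits that left out 1 array. It was lost in the authors' value table, under quantile normalization and with normexp (limma adjusted p = 0.0677, 0.106 and 0.123). Extracellular matrix genes had 1 of 32 higher (1 adjusted over the list alone), the protease inhibitor gene Timp1 at 1.99-fold (adjusted p = 0.634 with an estimated correlation). Cholesterol synthesis genes had a median of 0.16 with 0 of 25 past the threshold (0 adjusted over the list alone, adjusted p = 0.875 with an estimated correlation). Their call was lost in the authors' value table, under quantile normalization and with normexp, at medians of 0.098, 0.14 and 0.14 (camera adjusted p = 0.534, 0.426 and 0.321). It was also lost with array weights (0.0790) and the filter on all 8 arrays (0.0528). Of phase II conjugation genes, 5 rose and 3 fell of 33 (8 and 3 adjusted over the list alone, adjusted p = 0.875 with an estimated correlation), with the glucuronosyltransferase genes Ugt2b37 and Ugt2b5 at 1.68-fold and 1.49-fold and the sulfotransferase gene Sult1c2 falling by 1.07 on the log2 scale. The conjugation call was lost in the authors' value table, with normexp and under quantile normalization, at medians of 0.051, 0.046 and 0.13 (camera adjusted p = 0.881, 0.504 and 0.561). Array weights, the filter on all 8 arrays and the shift by the brightest 25% of genes ended it too (0.229, 0.147 and 0.0735). Sinusoidal endothelial markers had a median of -0.18 with 0 of 24 past the threshold (0 higher and 3 lower adjusted over the list alone), and exocrine pancreas markers a median of -0.48 with 0 of 12 past it (0 adjusted over the list alone). Their adjusted p with an estimated correlation was 0.634 and 0.623, and with a median shift their medians were above 0, at 0.31 and 0.01, where the median of all genes was 0.39. The exocrine pancreas call was lost in the authors' value table, with normexp and under quantile normalization, at medians of -0.085, -0.090 and -0.19 (adjusted p = 0.191, 0.208 and 0.299).

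Leaving out 1 array ended 6 of those 10 calls. Without vehicle replicate 2 the adjusted p was 0.189 for oxidative phosphorylation, 0.258 for conjugation and 0.143 for exocrine pancreas. Without vehicle replicate 4 it was 0.0509 for DNA repair, 0.0842 for cholesterol synthesis and 0.0775 for conjugation, and without vehicle replicate 3 it was 0.0575 for extracellular matrix. Without furan replicate 41 it was 0.140 for cholesterol synthesis, 0.0793 for conjugation and 0.0671 for exocrine pancreas, without furan replicate 43 0.0673 for cholesterol synthesis, and without furan replicate 44 0.0504 for DNA repair, 0.0656 for conjugation and 0.0642 for extracellular matrix. Without vehicle replicate 4 the DNA repair median went from 0.15 to 0.081, the conjugation median from 0.12 to 0.025 and the extracellular matrix median from 0.084 to 0.16. Without furan replicate 43 the DNA repair median was 0.062, without furan replicate 41 the cholesterol synthesis median went from 0.16 to 0.076, and without vehicle replicate 2 the oxidative phosphorylation median went from 0.076 to 0.040.

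Of the cell type marker lists, only those of sinusoidal endothelium and exocrine pancreas, given above, passed camera. Kupffer cell and macrophage markers had a median log2 fold change of -0.07 over 28 genes, against a mean of 0.02 and an upward test (adjusted p = 0.497). Without vehicle replicate 4 that list passed, with a median of 0.20 and an adjusted p of 3.9e-05. T and NK cell markers had a median of -0.24, B and plasma cell markers -0.23, neutrophil markers 0.01 and erythroid markers -0.14, with 0 members past the threshold in each. Adjusted over the list alone, 1 neutrophil marker was higher and the other lists had 0. Among 25 cholangiocyte and progenitor markers the median was 0.05 and 2 rose (2 adjusted over the list alone), the cytokine receptor gene Tnfrsf12a at 3.51-fold and the stem cell marker gene Prom1 at 2.22-fold. The bile duct marker gene Epcam did not pass (log2 fold change -0.93 ± 0.71, adjusted p = 0.416). Without vehicle replicate 2 the Epcam value was -0.23 (adjusted p = 0.752). Among 22 stellate cell markers the median was 0.04 and 1 rose (1 adjusted over the list alone). Among 9 adipocyte and muscle markers 1 rose (1 adjusted over the list alone), the lipid droplet gene Cidec at 3.01-fold, against a list median of -0.50. The Cidec call held in 1 of the 8 fits that left out 1 array and in 8 of 15 other settings. It was lost under quantile normalization (limma adjusted p = 0.0679) and with the mean of its probes, at a log2 fold change of 1.06 (0.0783). A median shift, no shift, no filter and the slide row or column as a block ended it too.

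Beside the oxidative phosphorylation, cholesterol and conjugation lists given above, no metabolic or zonation list passed camera. Cyp2e1, the enzyme known to oxidise furan, showed a log2 fold change of -0.11 ± 0.13 (adjusted p = 0.615), and one of 0.38 with a median shift, 0.02 without a shift and 0.02 with normexp. The lowest Cyp2e1 value over all alternatives was -0.26, and none put the gene past the threshold (lowest limma adjusted p 0.212). Of 34 cytochrome P450 genes, 1 rose and 2 fell (2 and 2 adjusted over the list alone), Cyp3a16 rising 1.95-fold, Cyp2g1 falling by 1.17 on the log2 scale and Cyp2j5, named after its value was seen, by 0.50. Of 37 fatty acid oxidation genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone), and the hormone gene Fgf21 was 3.58-fold higher. The lipogenesis list had 2 of 25 higher (3 higher and 1 lower adjusted over the list alone), the glycerolipid genes Gpam and Pnpla3, and Pnpla3 had a second probe at -0.62. The median of that list was -0.07 and its test ran upward (adjusted p = 0.961). Of 30 amino acid and urea cycle genes 1 fell (4 higher and 3 lower adjusted over the list alone), the proline oxidase gene Prodh. Of 25 periportal genes 1 fell (1 and 1 alone), the steroid dehydrogenase gene Hsd17b6, and of 26 pericentral genes 1 rose (1 alone), the carboxylate transporter gene Slc13a3. The calls of Gpam, Pnpla3 and Prodh held in 0 of the 8 fits that left out 1 array. Those of Fgf21, Cyp3a16, Hsd17b6 and Slc13a3 held in 1 each, and that of Cyp2g1 in 5. With the mean of its probes Pnpla3 was at 0.08 (limma adjusted p = 0.883). Bile acid genes had 0 of 26 past the threshold and gluconeogenesis genes 0 of 22, with 0 in each when adjusted over the list alone. The medians of the amino acid, gluconeogenesis and periportal lists were -0.04, -0.07 and -0.06 while their tests ran upward. Of these metabolic and zonation lists, 7 passed camera as lower in the authors' value table: pericentral genes at a median of -0.23 (adjusted p = 0.000248), P450 genes at -0.20, fatty acid oxidation genes at -0.18, gluconeogenesis genes at -0.17, bile acid genes at -0.16, periportal genes at -0.16 and amino acid and urea cycle genes at -0.15. Pericentral and fatty acid oxidation genes passed as lower under quantile normalization too, at medians of -0.17 and -0.10. With normexp, pericentral (-0.16), fatty acid oxidation (-0.092) and bile acid genes (-0.12) passed as lower.

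Of 19 circadian clock genes 1 rose (2 adjusted over the list alone), the core clock activator gene Arntl at 4.89-fold, with vehicle values of -2.15 ± 0.92 and furan values of 0.13 ± 0.21. Its call ended in 6 of the 8 fits that left out 1 array. Of 35 interferon-stimulated genes 1 rose (1 alone), the chemokine gene Cxcl10 by 1.69 ± 0.15, and the inflammatory cytokine list had 0 of 27 past the threshold (1 higher and 1 lower alone). Of 33 acute phase genes 1 rose (4 alone), the metalloreductase gene Steap4. Of 31 apoptosis regulators 3 rose and 2 fell (5 and 3 alone). Tnfrsf10b, Tnfrsf12a and the apoptosis effector gene Bax were up and the BH3-only gene Bmf and the caspase gene Casp6 were down, Bax and Casp6 being named after their values were seen. Among 22 female-biased liver genes 3 rose and 1 fell (3 and 4 alone). Those that rose were Prom1, Cyp3a16 and the organic anion transporter gene Slc22a27, the last of them named after its value was seen, and the sulfotransferase gene Sult3a1 fell by 1.18 on the log2 scale. Among 21 male-biased genes 2 rose and 1 fell (3 and 2 alone), the glutathione transferase gene Gstp1 and Ugt2b38 rising and Elovl3 falling. In each of these counts, alone means adjusted over the list alone. The clock and acute phase medians were -0.03 each and the inflammatory cytokine median -0.00, while their tests ran upward. Without vehicle replicate 4 the interferon list passed at an adjusted p of 0.0330, and without vehicle replicate 3 the apoptosis list passed at 0.0494. The apoptosis list also passed camera with each probe on its own, with a median shift and without a filter (adjusted p = 0.0209, 0.0293 and 0.00280). Male-biased genes passed as lower in the authors' value table, at a median of -0.19.

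Outside these lists, the largest increase was that of Dppa5a, a pluripotency-associated gene. Its probe was not well above background on any vehicle array, and in the 75th percentile scaling of the processed signal it rose at least 12.1-fold, a bound taken against the lowest signal well above background on each vehicle array (adjusted p = 0.0143). In other settings the fold was smaller, at 5.18 with normexp and 6.74 in the authors' value table. Samd4, which encodes an RNA-binding translational repressor, was likewise dim in vehicle livers and rose at least 2.63-fold by the same bound, but 1.80-fold with normexp and 2.14-fold in the authors' value table. The growth factor gene Nrg1 rose by 2.84 ± 0.36, by 2.15 with normexp and by 2.24 in the authors' value table, and the call held without any 1 array. Ccdc120 was 5.85-fold higher, 2.49-fold with normexp and 2.81-fold in the authors' value table, and was well above background on 2 of the 4 vehicle arrays. The Ccdc120 call held only without vehicle replicate 2 and without furan replicate 42, with adjusted p of 0.0652, 0.0672 and 0.0740 without vehicle replicates 3, 4 and 6 and 0.0825, 0.0784 and 0.0766 without furan replicates 41, 43 and 44.

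Among genes that fell, Rad51b, a gene of homologous recombination, dropped by 1.62 ± 0.15 on the log2 scale (adjusted p = 0.00501), and Pcp4l1 dropped by 1.41 ± 0.17. Both calls held without any 1 array. The flagellin receptor gene Tlr5, the potassium channel gene Kcnk10 and Bmf, of the apoptosis list, were 2.82-fold, 2.70-fold and 2.88-fold lower, Tlr5 1.79-fold with normexp. Cpsf4l was 3.62-fold lower. Without vehicle replicates 3, 4 and 6 the adjusted p was 0.0568, 0.0527 and 0.0590 for Tlr5, 0.0581, 0.0636 and 0.0635 for Bmf and 0.0515, 0.0539 and 0.0530 for Cpsf4l. Tlr5 was also lost without furan replicates 41 and 44 (0.0715 and 0.0517), Bmf without furan replicates 41, 42 and 44 (0.0642, 0.0674 and 0.0605), Cpsf4l without furan replicates 43 and 44 (0.0531 and 0.0559) and Kcnk10 without furan replicate 41 (0.0566). Vmn2r97, a vomeronasal receptor gene, was not well above background on any furan array and was at least 1.78-fold lower, and Methig1 was 2.65-fold lower, both in the 75th percentile scaling. Vmn2r97 thus passed the filter only through the vehicle arrays, and its receptor class is treated below as silent in liver. The calls of Vmn2r97 and Methig1 were lost under quantile normalization at log2 fold changes of -0.57 and -0.75 (adjusted p = 0.569 and 0.470), with normexp at -0.14 and -0.33 (0.506 and 0.321) and in the authors' value table at -0.18 and -0.42 (0.433 and 0.164). With trend and robust, Vmn2r97 was lost at an unchanged -1.43 (0.0708). Methig1 was also lost without furan replicates 41 and 43 (0.0503 and 0.0513). Glyceraldehyde phosphate dehydrogenase and beta-actin, commonly used references, showed log2 fold changes of 0.10 ± 0.10 for Gapdh (adjusted p = 0.524) and 0.26 ± 0.09 for Actb (adjusted p = 0.149), the Gapdh value being -0.00 in the authors' value table.

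**Figure D4:**
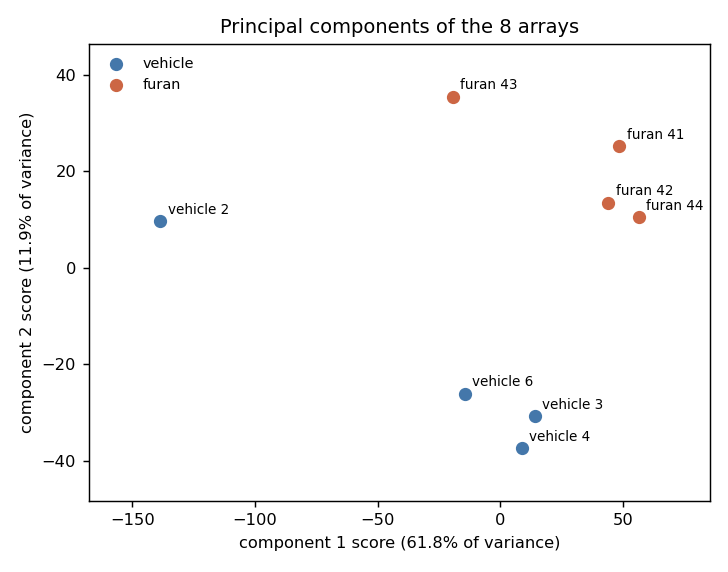
Each dot is 1 array placed by its scores on the first and second principal components of the tested genes, with 4 vehicle and 4 furan arrays coloured by group. Vehicle replicate 2 lies alone at -138.5 on the first component, and the second component separates the furan arrays from the other 3 vehicle arrays.

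The number of calls depended on which array was left out and on the scaling. Without vehicle replicates 2, 3, 4 and 6 there were 927, 401, 306 and 295 calls, and without furan replicates 41, 42, 43 and 44 there were 195, 245, 195 and 259. Of the 79 named genes past the threshold, 31 stayed past it in all 8 of these fits, 12 in 4 to 7 and 36 in under 4, none with a change of sign, and the highest adjusted p was 0.130, for Gusb. The number of the 79 that lost the call was 14, 32, 34 and 34 without vehicle replicates 2, 3, 4 and 6, and 40, 35, 43 and 37 without furan replicates 41, 42, 43 and 44. Dppa5a lost it without furan replicate 43 alone (adjusted p = 0.0534), and Ect2 and Kcnk10 without furan replicate 41 alone (0.0525 and 0.0566). Chordc1, Hsph1 and Methig1 lost it without furan replicate 41 (0.0503, 0.0567 and 0.0503) and without furan replicate 43 (0.0518, 0.0538 and 0.0513). The label text names a randomized block design without giving the blocks. With the slide column as a block, limma called 0 genes, 4723 having an unadjusted p under 0.05, against 5931 without the block, and 0 of the 79 named calls held. The lowest adjusted p was then 0.0714, the fold changes did not move, and the total degrees of freedom fell from 7.86 to 4.76. With the slide row as a block there were 810 calls. Within the rows, each with 2 vehicle and 2 furan arrays, 0 genes passed in limma, with 2247 in row 1 and 3962 in row 2 at an unadjusted p under 0.05. The p53 target median was 1.00 in row 1 and 0.91 in row 2, the NRF2 median 0.65 and 0.44, and the G2/M median 1.33 and 0.58. The shift by the brightest 25% of genes was chosen after the data were seen. The share of calls that were higher was 68.6% in the 75th percentile scaling, 61.1% under quantile normalization, 88.1% without a shift, 98.8% with a median shift and 43.3% with a shift on the brightest 25% of genes. The median log2 fold change of all tested genes was -0.09, 0.04, 0.03, 0.39 and -0.20 in the same order. Relative to the median of all tested genes in the 75th percentile scaling, the list medians were 1.04 for p53 targets, 1.01 for G2/M, 0.75 for immediate early genes, 0.66 for NRF2 targets and 0.63 for fetal and tumour-associated genes. These lists had higher medians and passed camera with the preset correlation under each scaling run, with adjusted p = 0.0626 with an estimated correlation for p53 targets, immediate early and fetal genes, 0.173 for NRF2 targets and 0.409 for G2/M.

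Vehicle replicate 2 stood apart from the other arrays. Its median processed signal was 130.4 against 32.5 to 48.2 on the other 7, and its 25th percentile 53.9 against 4.67 to 13.9. The first principal component, with 61.8% of the variance, held this array at -138.5 against -19.4 to 56.5 for the others. Its mean correlation across genes with the other vehicle arrays was 0.965, against 0.981 to 0.985 for each of them with its group, and genes are not independent replicates. Without it, the number of higher and lower genes was 603 and 324, and 722 of the 1041 genes were called again.

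**Figure D5:**
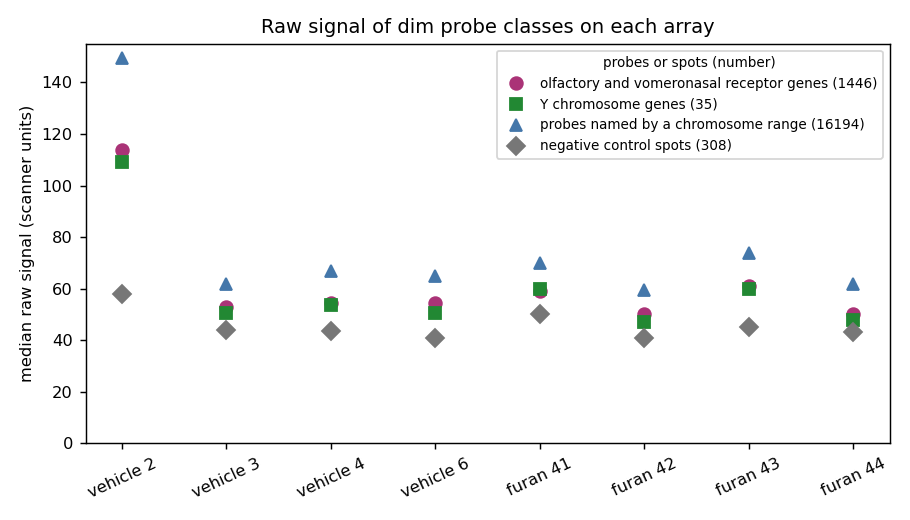
Each marker is the median raw signal in scanner units of 1 class of dim probes or control spots on 1 of the 8 arrays. On vehicle replicate 2 the receptor, Y chromosome and chromosome-range probes lie at 113.8, 109.0 and 149.5, above their values on each other array.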

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

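The tests of the scanner background, of vehicle replicate 2 and the scaling for the brightly expressed lists, and of immune cells and vehicle replicate 2 for the mitosis list were chosen after the results were seen. In 16 of 194 groups of 4 arrays, 1 array lay far from the other 3, where chance gives about 1 in 20 groups, or 9.7. Of these, 11 were among 174 groups of values of named genes, and 2 of the 11 were on vehicle replicate 2. Values of genes are log2 signals relative to the 75th percentile of the array.

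Among vehicle arrays, Atf3 was at -0.69 and Aen at 4.31 on replicate 4, with the nearest other arrays at -1.68 and 4.18. Golm1 was at 0.60 on vehicle replicate 4, nearest other 0.35. Psat1 was at -3.55 on vehicle replicate 6, nearest other -2.71. Fen1 was at 0.59 and Epcam at -0.53 on vehicle replicate 2, nearest others 0.36 and -3.06. Among furan arrays, Chordc1 was at 2.85, Cyp2g1 at 1.92 and Hmox1 at 5.48 on replicate 41, nearest others 2.64, 1.52 and 3.91. Tfrc was at 0.21 on furan replicate 44, nearest other -0.54, and Myc at 0.45 on furan replicate 43, nearest other -0.56. Furan replicate 43 also had a 25th percentile of processed signal of 13.9, nearest other 5.72, and a score of -19.4 on the first principal component, nearest other 44.1. On vehicle replicate 2 the median processed signal was 130.4, the 25th percentile 53.9 and the median of the authors' log2 values 6.74, with nearest others at 44.8, 10.8 and 6.55.

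The first pattern is the raised dim signals on the array of vehicle replicate 2. Genomic DNA in the labelled sample would raise probes of olfactory and vomeronasal receptor genes, silent in liver, more than probes of Y chromosome genes, which female mice lack, but the difference was -0.00341 log2 (95% bootstrap interval -0.987 to 0.421). A rise of scanner and slide background is argued against by the negative control spots, which gained 30.5% of the raw signal that the receptor probes gained. Probes of Y chromosome genes were raised by 2.39 log2 (interval 1.95 to 3.24), so nonspecific binding of labelled material to mouse probes may account for the raise and stays open. No biological explanation was tested, since the pattern lies within 1 group.

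The second pattern is the small rise of the ribosomal protein, proteasome, oxidative phosphorylation and control gene lists. Without vehicle replicate 2, 3 of the 4 lists passed camera with the preset correlation, all but oxidative phosphorylation. Such a pass separates little. With all arrays, 7 of 35 splits gave a camera p as small for ribosomal genes, the real one included. That number was 6 for proteasome, 6 for control and 16 for oxidative phosphorylation genes. For ribosomal, proteasome and control genes the medians alone argue against this array as the whole cause. Over the fits without 1 array, the lowest was 0.099 for ribosomal, 0.12 for proteasome and 0.10 for control genes. The oxidative phosphorylation median fell from 0.076 to 0.040 without vehicle replicate 2, its lowest in these fits. For that list the medians therefore do not argue against this array. With all arrays the camera adjusted p was 0.680 with an estimated correlation for ribosomal and proteasome genes, 0.623 for control genes and 0.913 for oxidative phosphorylation. The scaling between arrays may account for part of the pattern or for all of it, since 0 of the 4 lists passed camera in the authors' value table. Under quantile normalization and normexp the ribosomal protein and control gene lists still passed and the other pair did not, and all 4 passed with a median shift and without a shift. An effect of furan stays open as well.

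The third pattern is the rise of G2/M and mitosis genes. A larger share of immune cells in proportion to it is argued against by the 4 immune cell lists, whose highest median log2 fold change was 0.0101, although the macrophage list stood at 0.20 without vehicle replicate 4. Vehicle replicate 2 is argued against by a median of 1.07 without it, and chance by the splits, where 1 of 35, the real one, had a median as far from that of all genes, 1.01 against at most 0.92 in another split. By the camera p, however, 4 of 35 splits were as extreme. A furan effect on dividing liver cells may account for the rise, as a hypothesis, and which cells divided was not measured.

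For the counts of genes, a random regrouping without blocks was argued against, at the lowest share that 35 splits can give. Only 1 of 35, the real one, gave as many as 1041 genes past the threshold, 714 higher, 327 lower or 631 changed 1.5-fold. Every other split gave 0 in limma, with at most 2737 genes at an unadjusted p under 0.05, against 5931. The splits take no account of the slide columns, and with the column as a block the real groups gave 0 genes in limma and 4723 at an unadjusted p under 0.05. If the column was the block of the design, these splits cannot exclude chance. Chance was not excluded for the number of gene lists, 18, because 16 of 35 splits gave as many and the highest other split gave 27. For p53 targets, NRF2 targets, heat shock, immediate early and fetal and tumour-associated genes, the real split alone was as extreme both by the median and by the camera p.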

How the results depend on the processing

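The shift by the brightest 25% of genes and the fit of the brighter 50% of genes were chosen only after the data were seen. The 79 named genes past the threshold, of which 72 had a value with the filter on all 8 arrays, had the same direction under each alternative run on named genes, with 1 exception: Fosl2 went to -0.015 (adjusted p = 0.984) with the mean of its probes. With trend and robust, the slide row or column as a block, and each probe on its own, the tested probe kept its fold change. The direction could therefore not differ in those fits. Other kept probes of Cdkn1a, Mad2l1, Fosl2 and Pnpla3 included 1 of the opposite direction for each gene, as given above. Leaving aside the results that reversed, values of named genes were on the same side of the threshold in 1447 cases, newly past it in 8 and no longer past it in 538. For the lists these numbers were 925, 19 and 77. In the authors' value table the gluconeogenesis, amino acid and urea cycle, periportal and oxidative phosphorylation lists had medians of -0.17, -0.15, -0.16 and -0.036, and camera ran downward. The first 3 had medians of -0.07, -0.04 and -0.06 before, with camera running upward, so that only the direction of their test reversed. For oxidative phosphorylation the median, 0.08 before, reversed too.

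Counts of genes are given as past the threshold, higher, lower and past with 1.5-fold. The median shift gave 86, 85, 1 and 86, no shift 261, 230, 31 and 259, no filter 163, 124, 39 and 163, and an adjusted p under 0.01 101, 82, 19 and 101. The slide column as a block gave 0, 0, 0 and 0 in limma, with 4723 at an unadjusted p under 0.05. The first 3 counts were 1668, 1109 and 559 in the authors' value table, 1733, 1155 and 578 with the filter on all 8 arrays, 2001, 1437 and 564 with trend and robust, 2043, 1240 and 803 with array weights, and 2135, 1594 and 541 over the brighter 50% of genes. Lower genes numbered 502 with normexp and 721 with the shift by the brightest 25% of genes. The 1.5-fold count was 22 with treat and 197 at 2-fold. Of the 18 lists past the threshold, 0 passed with an estimated correlation and 7 with fry. Leaving out 1 array gave 195 to 927 past the threshold, 142 to 603 higher, 48 to 324 lower, 194 to 631 with 1.5-fold, and 15 to 18 lists. The cause was not tested, except that the block and the fits without 1 array have fewer degrees of freedom and the thresholds are stricter by construction. No paired analysis was possible because the groups share no replicate numbers, except by position, which is the fit with the slide column as a block. Signal over background limits the dim genes, most of all on vehicle replicate 2, where 86.2% of spots counted as well above background.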

Other observations

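The lists in this part, and their tests, were all chosen after the values were seen. Of ribosome biogenesis factors, which build ribosomal subunits, 22 of 122 measured members rose and 0 fell (57 and 0 adjusted over the list alone), with a median log2 fold change of 0.30. The other members did not pass the threshold over all genes. Nop58, a core protein of small nucleolar particles, rose by 0.98 ± 0.13 (SE, limma adjusted p = 0.0136), the nucleolar helicase gene Ddx21 by 0.93 ± 0.12, and Nob1, which matures the small subunit, by 0.86 ± 0.10. The unadjusted camera p was 4.98e-21 with the preset correlation and 0.0199 with an estimated one. Neither was adjusted over lists, so they cannot be set against the adjusted p of the 41 fixed lists. Without the 7 genes that were seen first, 15 of 115 rose (unadjusted camera p = 0.0250 with an estimated correlation). Only the real split of 35 had a median as far from that of all genes, 0.39 against at most 0.25. The number that rose was 18 without vehicle replicate 2, 18 under quantile normalization, 37 in the authors' value table and 0 in limma with a median shift, where the median was 0.78.

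Of 18 measured tubulin genes, which encode the subunits of microtubules, 6 rose and 0 fell (7 and 0 adjusted over the list alone), led by Tubb2a at 5.18-fold (adjusted p = 0.00306), Tuba1c at 2.28-fold and Tubb4b at 2.27-fold. The median log2 fold change was 0.17. The camera p, again unadjusted, was 5.64e-05 with the preset correlation and 0.0509 with an estimated one. In 2 of 35 splits, the real one included, the median was as far from that of all genes. The number that rose was 6 without vehicle replicate 2, 5 under quantile normalization and 6 in the authors' value table. With a median shift it was 1 in limma. The medians were 0.22, 0.37, 0.14 and 0.65 in that order. Without the genes seen first, 3 of 15 rose and 9 of 35 splits had a median as far from that of all genes, the real one included.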
